A study of Mus musculus with 5 samples.

How the data were processed

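Poly(A) RNA from 5 C57BL/6J mouse embryonic tissues was sequenced as paired-end libraries on the Illumina HiSeq, per the labels' protocols, with 1 library per tissue. The tissues were foregut and medial foregut at embryonic day 8.5 (E8.5) and liver, ventral pancreas and dorsal pancreas at E10.5. The first cDNA strand was primed with random hexamers and no strand marking is described in the labels' protocols, so reads of overlapping genes on opposite strands cannot be told apart. How the tissue was isolated is not given in the sources used here.

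The authors deposited 1 table of FPKM values (fragments per kilobase of transcript per 1000000 mapped fragments), per the file headers. The submitters' processing notes name TopHat 1.33, Cufflinks 1.3.0 and the mouse build mm9, with no role or order; the scaling between libraries and the rule by which loci entered the table are not given in the sources used here. Each column was assigned to its tissue by the column name that the sample's own label repeats. The table held 14053 loci with an identifier, a chromosome interval, a strand and a short gene name, and the lowest maximum over the 5 libraries was 0.235 FPKM. A name was missing for 1678 loci, which entered no comparison, and 12375 named loci were analysed. Of these, 731 carried several joined gene names, 187 had no strand and 278 spanned under 1000 bp.

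Coordinates are those of the table, in mm9, and whether the start counts from 0 or 1 is not stated there. The reference annotation at hand was on another assembly (the highest end on chromosome 7 was 152470065 in the table and 145324059 in the GRCm38 gene table), so it was used for names, strand and span only. Of 13001 names, 11660 were current symbols and a further 1273 were synonyms in the GRCm38 gene table. By name, 10555 loci matched 1 gene of GENCODE M21 (GRCm38). Among the 10409 of these with a strand, 90 lay on the other strand than the annotated gene, and 756 matched loci covered under 30% of the annotated span. Where a gene named in the text is of either kind, this is stated beside it.

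Depth in reads is unknown. Low values were searched for whole-read steps, and between foregut and medial foregut the most common ratio was shared by only 11 of 187 loci at low values in both, so no count was recovered and no interval or floor is given. A value of exactly 0 is reported as listed at 0, and no ratio is given against it.

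With 1 library per group there are no replicates, no test and no p-value. Differences are on the log2(FPKM + 1) scale, which understates the change of low genes. A gene was counted as higher or lower when the difference was at least 2 in size (4 times in FPKM + 1) and the higher library reached 5 FPKM. The 6 comparisons were liver against both pancreatic libraries, ventral against dorsal pancreas, foregut against medial foregut, and each of the 3 E10.5 libraries against both E8.5 libraries. A comparison against 2 libraries required the same direction against each. A further count took genes higher in 1 library than in each of the other 4. Comparisons that share a library share its chance values, so no overlap between them was tested, and a gene or list named in several of them is description only.

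There were 36 gene lists, fixed before the data were examined together with the comparisons, the size rule and the alternatives. They covered lineages, signalling pathways and markers of other cell types that such tissue can hold. Members were found by exact gene name or a listed synonym. Those with no such locus, or only within a joined name, were not measured. Of 33 hepatic secreted genes listed 21 were found, of 27 Hox genes 7, of 18 erythroid genes 7 and of 15 leukocyte genes 5. Found members with a mean of at least 1 FPKM over the 5 libraries were called measured. The median difference of the measured members was placed among 10000 random lists of the same size, drawn from the other loci and matched on mean expression in 20 bins (seed 1). This percentile describes these libraries and is no test. Lists with fewer than 5 measured members got no percentile. Over 32 lists and 10 pairs of libraries, 206 of 320 percentiles lay outside the middle 95%, where randomly drawn lists would give 16. Genes of 1 list can vary together, some lists share members and the pairs share libraries. The excess over 16 is therefore not evidence of its own.

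Genes named in the text follow a rule fixed beforehand: for liver against pancreas the 15 highest and 15 lowest by the smaller of the 2 differences, for the other comparisons 12 and 12 (6 and 6 for dorsal pancreas against E8.5), up to 4 members of each list with the largest differences, and a short set of lineage and Wnt genes named always. Outside the rule, Hcn4, Shox2 and Krt8 are named because a prediction named them before their values were looked up, and Vsnl1 was chosen after its values were seen. Afp, which the rule always names, is not analysed here, and some genes that the rule takes are not reported here.

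The alternatives were pseudocounts of 0.1 and 5 FPKM, no floor or a floor of 10 FPKM, rescaling to a total of 1000000, rescaling by median ratios, loci listed at 0 left out, 1 comparison library at a time, list means, unmatched random lists, and list members at a mean of 5 FPKM or more. After seeing the data, 3 more were added: unstranded, short and joined loci left out (1141 loci), loci on the other strand or partial left out, and a hepatic share of the liver library subtracted from the ventral pancreas. The counting and list steps were tested on simulated data for liver against ventral pancreas over 12375 loci with a noise SD of 0.3. Of 100 genes changed 8 times, 96 were found in the right direction. Of 100 changed 2 times, which is below the size rule, 0 were counted, and 0 unchanged loci were counted. The noise SD was chosen, since without replicates it could not be estimated. These outcomes therefore check that the steps run as written. They cannot show how many unchanged genes are counted in the real libraries, whose noise is unknown. A simulated list of 20 genes shifted by 0.5 reached percentile 100, and an unshifted list 87.88. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.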

Results

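Gene expression was measured in 5 mouse embryonic tissues around the time when liver and pancreas arise from the foregut endoderm, the anterior part of the embryonic gut tube. At E8.5 the foregut and its medial part were profiled, and at E10.5 the liver, the ventral pancreas and the dorsal pancreas. The ventral pancreas arises beside the liver from ventral foregut endoderm, and the dorsal pancreas from the opposite side of the gut. There was 1 library per tissue and no replicate, so no difference could be set against replicate error, no test was run, and all values describe these libraries. Between 10266 named loci in liver and 11165 in ventral pancreas reached 1 FPKM. The summed FPKM of all loci was 456635 in foregut, 506529 in medial foregut, 503182 in liver, 473170 in ventral pancreas and 437581 in dorsal pancreas, and depth in reads is unknown.

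Across genes, the foregut and medial foregut libraries were closest (Spearman's rho 0.986), followed by ventral and dorsal pancreas (0.937). Liver lay closer to ventral pancreas (0.891) than to dorsal pancreas (0.857). Dorsal pancreas stood nearer to the E8.5 foregut (0.902) than ventral pancreas (0.877) or liver (0.860). These coefficients run across genes, which are not independent replicates. The median difference over all genes was -0.16 for liver minus ventral pancreas and -0.15 for liver minus dorsal pancreas, and rescaling by median ratios shifted these by 0.13 and 0.12. List medians are therefore read against random lists from the same pair of libraries.

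The first comparison was prompted by the title's question, what distinguishes hepatic from pancreatic progenitors. It set tissue libraries against each other, and markers of other cell types, given below, also differed between them. In the liver library 129 genes were higher and 187 lower than in both pancreatic libraries. With each library rescaled to a total of 1000000 the numbers were 151 and 415, so the higher share was 26.7% in place of 40.8%. Median-ratio rescaling gave 145 and 154, and a pseudocount of 5 FPKM gave 56 and 36, which turns the balance. Many genes for proteins that the liver secretes into the blood were on the higher side. A merged locus and the muscle genes Actc1, Myl4 and Acta2, given below, differed more by the smaller of the 2 differences. Of 21 measured members of the hepatic secreted list, 18 were higher in liver, and the list's median difference was 2.98 against ventral and 5.47 against dorsal pancreas, both at percentile 100 of random lists. Alb, which encodes serum albumin (chromosome 5, 90889928 to 90905626), stood at 1051 FPKM in liver, 97.0 in ventral pancreas and 1.497 in dorsal pancreas. Trf, encoding transferrin, stood at 1244, 115 and 27.2 FPKM, the apolipoprotein gene Apoa1 at 618, 45.8 and 1.97, and Serpina6, encoding corticosteroid-binding globulin, at 603, 43.5 and 6.39. Apoc2, Hpx, Kng1 and Serpind1, all for plasma proteins, were among the 15 highest differences, as were Csrp3, Gchfr and Tnni1. The 3 members not counted were Ttr, Ambp and Vtn. Ambp, for example, stood at 898 FPKM in liver, 612 in ventral and 188 in dorsal pancreas. Ttr, at 16.7, 12.3 and 5.67 FPKM, is a locus on the other strand than the annotated gene.

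The list of hepatic transcription factors stood apart from random lists in liver against dorsal pancreas. Its median difference was 1.96 against dorsal pancreas (percentile 100) and -0.14 against ventral pancreas (percentile 71.75). Against ventral pancreas the mean of the members was 0.23 (percentile 98.03), of the other sign and past the limit. Only Hnf4a and Creb3l3 of the 13 measured members were higher in liver than in both, and 11 were neither higher nor lower. Hnf4a, a nuclear receptor of hepatocytes, stood at 158 FPKM in liver, 31.3 in ventral and 13.0 in dorsal pancreas. Hhex, a homeobox gene needed for liver and ventral pancreas budding, stood at 71.2, 133 and 10.6 FPKM. Prox1, at 30.3, 9.66 and 11.5 FPKM, is a locus on the other strand than the annotated gene.

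The transcription factors of pancreatic progenitors were lower in liver. The list's median difference was -2.80 against ventral and -1.51 against dorsal pancreas (percentile 0 in both), and 7 of 16 members were lower than in both: Pdx1, Ptf1a, Sox9, Nkx6-1, Mnx1, Rfx6 and Isl1. Pdx1 (chromosome 5, 148081169 to 148092911) stood at 0.0313 FPKM in liver, 39.2 in ventral and 40.9 in dorsal pancreas. Sox9 stood at 2.32, 37.0 and 25.3 FPKM and Mnx1 at 0.00610, 11.0 and 19.1. Nkx6-1 stood at 0.0138, 7.05 and 13.1 FPKM. Ptf1a was listed at 0 in liver and stood at 7.55 and 8.32 FPKM in the pancreatic libraries. Foxa2, shared by liver and pancreas endoderm, was at 24.0, 45.7 and 33.1 FPKM. Of the 18 measured endocrine genes, 8 were lower in liver and 10 were not counted, with medians of -2.10 and -4.06 (percentile 0 in both). Gcg, encoding glucagon (chromosome 2, 62312638 to 62321998), stood at 0.00929 FPKM in liver, 208 in ventral and 1349 in dorsal pancreas, and the hormone gene Pyy at 1.93, 167 and 722. Neurog3, which starts endocrine differentiation, stood at 0.00408, 2.74 and 7.86 FPKM and was not counted. Among the acinar genes, the carboxypeptidase gene Cpa1 was lower in liver and stood at 0.229, 27.0 and 30.7 FPKM.

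Epithelial genes were lower in liver as well. The list's medians were -2.07 and -0.80 (percentile 0 in both), and 10 of 25 members were lower than in both pancreatic libraries, with 15 not counted. Cdh1, encoding E-cadherin, stood at 14.0 FPKM in liver, 87.0 in ventral and 64.3 in dorsal pancreas, and Epcam at 28.4, 343 and 163. The tight junction gene Cldn3 stood at 0.401, 29.4 and 36.9 FPKM; Cldn4 has the same interval on the opposite strand, so their reads cannot be told apart without strand. Other genes with the largest differences were Nepn (0.512, 254 and 602 FPKM), the amino acid transporter gene Slc38a5 (0.655, 165 and 886), Spp1, encoding osteopontin (0.0101, 38.0 and 68.2), Abcc8, encoding the sulfonylurea receptor (0.0445, 18.9 and 49.3), and Col2a1 (2.01, 124 and 73.7). Chrna4, Chgb, Kcnk16 and Rhov were also among the 15 lowest in liver.

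**Figure D1:**
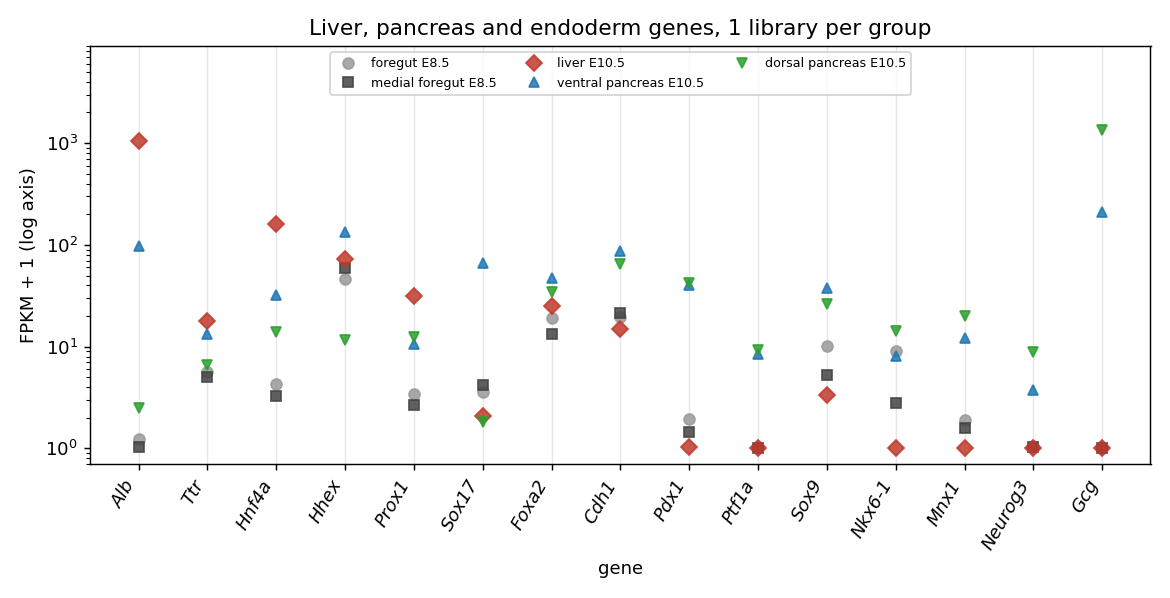
FPKM + 1 on a log axis for liver, pancreas and endoderm genes, 1 point per library and no error bars because there was 1 library per group. Alb was highest in liver at 1051 FPKM with 97.0 in ventral pancreas, and Gcg was highest in dorsal pancreas at 1349 FPKM.

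Markers of other cell types differed between the same libraries. All 5 measured leukocyte genes, of 15 listed, were higher in liver, with medians of 3.41 (percentile 100) and 2.72 (percentile 99.97). The complement gene C1qb stood at 41.3 FPKM in liver, 1.59 in ventral and 2.65 in dorsal pancreas. Cx3cr1 stood at 12.2, 0.245 and 1.005 FPKM at a locus that covers 0.287% of the annotated span. Of 15 cardiomyocyte genes, 7 were higher in liver, with medians of 1.67 and 2.61 (percentile 100 in both). The sarcomere genes Actc1 and Tnnt2 stood at 77.9 and 102 FPKM in liver, at 0.217 and 4.23 in ventral and at 0.752 and 0.388 in dorsal pancreas. Myl4 was at 124, 2.17 and 0.852 FPKM at a locus with 22.3% of the annotated span. Of 18 mesenchymal genes, the smooth muscle genes Acta2 and Tagln were higher in liver, and Acta2 stood at 133, 2.78 and 0.923 FPKM. That list's medians were 0.26 (percentile 99.64) and 0.04 (percentile 94.28). Endothelial genes had medians of 1.81 (percentile 100) and 0.41 (percentile 99.78), and none of 14 was counted against both pancreatic libraries. The mesothelium and septum transversum list had medians of 0.55 and 0.50 (percentiles 99.86 and 99.65) with 1 of 11 members, Tbx18, higher; among its 5 members at a mean of 5 FPKM or more, the medians were -0.72 and -0.86, with the opposite sign. The highest single difference was a merged locus of 3 names, 2410017I17Rik,H2-Bl,H2-T10 (chromosome 17, 36131114 to 36340317), at 4797 FPKM in liver, 2.37 in ventral and 0.508 in dorsal pancreas; which gene its reads came from cannot be told.

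Non-canonical Wnt and planar cell polarity components, listed for their part in signalling without beta-catenin, were on the whole lower in liver. The list is not specific to that branch, since 8 measured members, among them Fzd2 and Sfrp5, are also on another list. Of 42 measured members 6 were lower than in both pancreatic libraries, 0 were higher and 36 were not counted. The median difference was -0.51 against ventral (percentile 0.55) and -0.57 against dorsal pancreas (percentile 0.13). This list was prompted by the study's title and is not independent evidence of its direction. The call against ventral pancreas ended among the 28 members at a mean of 5 FPKM or more, where the median was -0.31 at percentile 5.56; against dorsal pancreas it was -0.53 at percentile 0.19. The receptor gene Fzd2 (chromosome 11, 102462882 to 102470261) stood at 3.04 FPKM in liver, 21.4 in ventral and 18.9 in dorsal pancreas. The co-receptor gene Ror2 stood at 4.06, 20.1 and 23.5 FPKM, and the polarity cadherin genes Celsr1 at 0.749, 7.74 and 7.03 and Celsr2 at 1.46, 8.94 and 9.77. The calcium-regulated factor Nfatc4 was at 4.52, 28.6 and 26.3 FPKM, and Sfrp5, a secreted Wnt inhibitor, at 4.28, 41.7 and 21.7. Vangl2 stood at 8.08, 16.6 and 19.7 FPKM, short of the size rule. The ligand Wnt5b was at 1.83, 6.77 and 13.8 FPKM and Wnt5a at 0.582, 1.53 and 1.20. Wnt11 differed the other way, at 2.13, 0.296 and 0.652 FPKM, at a locus with 6.65% of the annotated span.

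**Figure D2:**
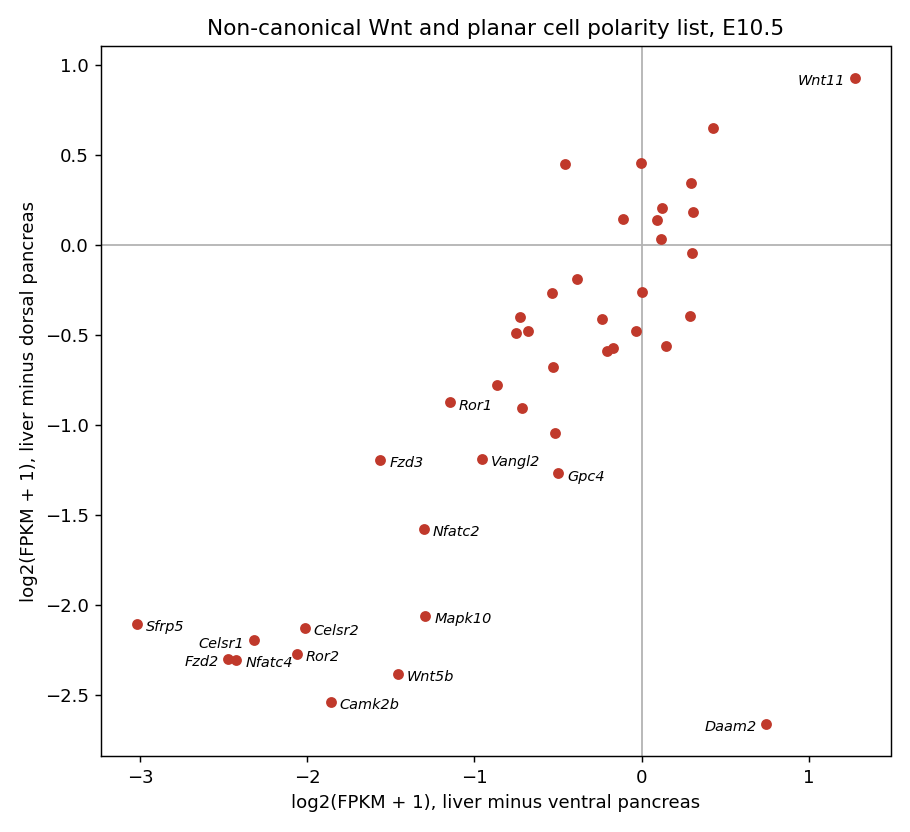
Each point is 1 of 42 measured non-canonical Wnt and planar cell polarity genes, by its log2(FPKM + 1) difference of liver minus ventral pancreas (horizontal) and liver minus dorsal pancreas (vertical). The medians were -0.51 and -0.57, and both axes share the liver library.

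Canonical Wnt components and targets did not stand apart from random lists, with medians of 0.02 (percentile 96.09) and -0.19 (percentile 53.62). With loci on the other strand or partial left out, the median against ventral pancreas was 0.14 (percentile 99.28). Among 28 members the receptor gene Lgr5 was higher in liver, at 22.9, 2.78 and 0.331 FPKM, and 27 were not counted. The target Axin2 stood at 8.19, 4.77 and 6.41 FPKM, and Lef1 at 1.38 in liver, 0.829 in ventral and 10.2 in dorsal pancreas. Of 6 measured Wnt ligands, Wnt7b was lower in liver (0.0196, 10.55 and 6.32 FPKM); the medians were -0.14 and -0.22, inside the middle 95%. Of 8 Frizzled genes only Fzd2 was lower, with medians of -0.67 (percentile 5.39) and -0.55 (percentile 10.67); the 6 at a mean of 5 FPKM or more had -0.86 (percentile 2.01) against dorsal pancreas. Of 8 secreted Wnt antagonists only Sfrp5 was lower, with medians of -0.28 (percentile 36.83) and -0.86, the latter below the middle 95% of random lists; the mean of the members against dorsal pancreas lay at percentile 20.06.

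The other signalling lists had medians below 0 in liver against both pancreatic libraries. Ephrins, semaphorins, slits and netrins, which guide axons and cell movement, had medians of -0.98 and -1.45 (percentile 0 in both), and 3 of 35 were lower in liver: Efna2, Sema3c and Sema3f. Sema3c stood at 0.884 FPKM in liver, 26.2 in ventral and 7.93 in dorsal pancreas. Notch genes had medians of -0.67 (percentile 1.36) and -0.77 (percentile 0.43), with Notch3 and Dll1 of 16 lower. Dll1 stood at 2.57, 20.7 and 17.9 FPKM. The FGF list had medians of -0.23 (percentile 42.48) and -0.66 (percentile 0.4), with the target Etv4 of 20 lower (8.83, 40.0 and 69.0 FPKM); its 15 members at a mean of 5 FPKM or more had -0.59 (percentile 0.99) against ventral pancreas. Hedgehog genes had medians of -0.46 (percentile 17.6) and -0.84 (percentile 0.96), and 0 of 13 were counted. The BMP and TGF-beta list had medians of -0.41 (percentile 3.21) and -0.27 (percentile 21.13), with 0 of 32 counted; its 26 members at a mean of 5 FPKM or more had -0.45 (percentile 0.81) against ventral pancreas. The retinoic acid list had medians of -0.02 and -0.08, inside the middle 95%, which became 0.09 and 0.03 under median-ratio rescaling, with Rxrg and Crabp1 of 13 lower in liver. The extracellular matrix list had medians of -0.30 (percentile 2.29) and -0.39 (percentile 0.85) with Lama1 of 20 lower; its means lay inside, at percentiles 3.24 and 5.27.

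**Figure D3:**
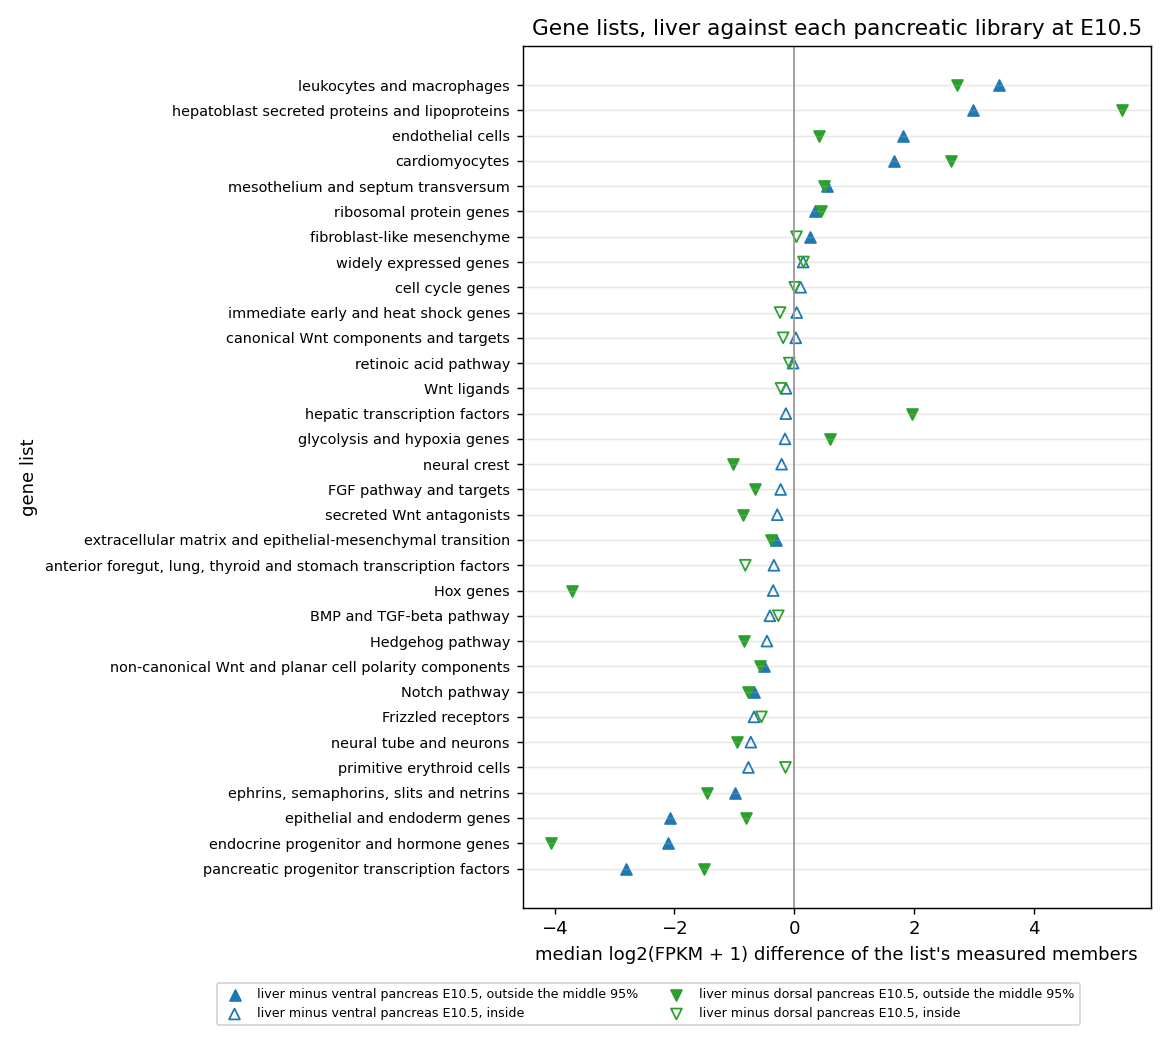
Median log2(FPKM + 1) difference of each gene list, liver minus ventral and liver minus dorsal pancreas, with filled markers outside the middle 95% of random lists. The hepatic secreted list lay at 2.98 and 5.47 and the pancreatic progenitor factors at -2.80 and -1.51; the mesothelium list turns negative among its 5 members at a mean of 5 FPKM or more.

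The second comparison set the 2 pancreatic buds against each other. In ventral pancreas 113 genes were higher and 95 lower than in dorsal pancreas. Genes of the hepatic lists stood on the ventral side: 13 of 21 secreted protein genes were higher, with a median of 2.31 (percentile 100), and 4 of 13 hepatic transcription factors, with a median of 1.62 (percentile 100). These 4 were Hhex, Cebpa, Onecut1 and Lhx2. Onecut1 is also on the pancreatic progenitor list, and Hhex stood higher in ventral pancreas than in liver. Apoa2 stood at 170 FPKM in ventral and 1.79 in dorsal pancreas, against 1618 in liver, and Cebpa at 18.0 and 2.82, against 47.3 in liver. Subtracting a hepatic share of the liver library from ventral pancreas, an alternative chosen after seeing the data, gave 80 higher and 122 lower, 39.6% higher in place of 54.3%. The same share was taken from every gene, and this can only lower ventral values. The direction of the shift was thus fixed in advance and says nothing about admixture. The largest ventral differences included Sntg2 (chromosome 12, 30859558 to 31058141) at 414 FPKM against 0.916, Hgf, encoding hepatocyte growth factor, at 84.6 against 0.816, and Sox17, an endoderm and biliary gene, at 65.9 against 0.821. Myo15 stood at 113 against 0.601 FPKM at a locus with 1.87% of the annotated span, and Bhmt at 31.9 against 0.668 with 3.96%. Uckl1 stood at 36.05 against 1.37 FPKM at a locus without strand. Reln, Paqr9 and Vstm2b were also among the 12 highest, with Reln at 103 against 1.47 FPKM.

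On the dorsal side stood genes of regional patterning and endocrine cells, and also endothelial and some mesenchymal genes. Which cells carried the Hox, FGF and Hedgehog differences given below was not tested. All 5 measured Hox genes, of 27 listed, were lower in ventral than in dorsal pancreas, with a median of -3.31 (percentile 0). Hoxb8 stood at 0.504 FPKM in ventral and 30.9 in dorsal pancreas. Hoxb3 (1.61 and 24.9 FPKM) is a locus on the other strand than the annotated gene, and Hoxa7 (1.24 and 14.1) covers 5.78% of the annotated span. Of 13 anterior foregut and stomach factors 5 were lower, with a median of -0.85 (percentile 0), among them the stomach mesenchyme gene Barx1 at 0.360 against 89.3 FPKM. Of 18 endocrine genes 5 were lower in ventral pancreas, with a median of -1.55 (percentile 0), and Ins1, encoding insulin, stood at 1.62 against 16.4 FPKM. The pancreatic progenitor factors had a median of 0.20 (percentile 96.06), or 0.46 (percentile 99.99) with loci on the other strand or partial left out; Onecut1 of 16 was higher in ventral (78.0 against 18.3 FPKM) and Isl1 lower (13.3 against 104). Mesenchymal genes had a median of -0.24 (percentile 0.47), with Pdgfra, Foxf1a, Nkx3-2 and Barx1 of 18 lower and Postn higher; among the 11 at a mean of 5 FPKM or more the median lay at percentile 30.16. Endothelial genes had a median of -1.47 (percentile 0), with 5 of 14 lower and Flt1 and Sox17 higher; Cdh5 stood at 1.37 against 10.7 FPKM. Tnc stood at 1.73 against 79.7 FPKM and Igf1 at 1.13 against 33.0. Nefl, Slc44a5, Sytl2, Aldoart2 and Six2 were also among the 12 lowest in ventral pancreas, and the Aldoart2 and Six2 loci cover 6.27% and 27.6% of the annotated span. The FGF list had a median of -0.53 (percentile 0), with Fgf9 (0.477 against 17.6 FPKM) and Fgf10 of 20 lower and Klb higher; the Fgf10 locus covers 0.742% of the annotated span. The Hedgehog effectors Gli1 (1.36 against 13.9 FPKM) and Gli2 of 13 were lower, with a median of -0.26 (percentile 1.2). Epithelial genes had a median of 0.90 (percentile 100), with Sox17 of 25 higher. The non-canonical Wnt list had a median of -0.12 (percentile 0.81), with Daam2 of 42 lower (0.728 against 17.3 FPKM); among the 28 members at a mean of 5 FPKM or more the percentile was 36.96. The canonical Wnt list had the same median of -0.12 (percentile 2.42), with Lef1 of 28 lower, and the mean of its members lay at percentile 10.96. Of 8 Frizzled genes Fzd5 was lower, with a median of 0.25 (percentile 94.18).

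At E8.5, foregut and medial foregut differed little by the size rule. Small list medians nonetheless lay past the percentile limits. They included hepatic secreted genes (0.17, percentile 99.82), hepatic transcription factors (0.29, percentile 99.96) and pancreatic progenitor factors (0.24, percentile 99.97). Endothelial genes (-0.38, percentile 0) lay on the other side. In foregut 5 genes were higher and 1 lower. The neural crest gene Sox10 stood at 8.10 FPKM in foregut and 0.560 in medial foregut, and the neural tube gene Olig2 at 11.3 and 1.31. Nr1h5 stood at 27.1 and 5.50 FPKM, Vit at 10.2 and 1.75, and the unstranded locus Uckl1 at 8.98 and 0.769. The lower gene was Aldoart2, at 244 against 13930 FPKM, at the same partial locus. Neural crest genes had a median of 1.34 and neural tube genes of 0.87 (percentile 100 in both), with 1 of 10 and 1 of 13 counted. The Hedgehog list had a median of 0.42 (percentile 100) and 0 of 13 counted. Cardiomyocyte genes had a median of -0.86 and mesenchymal genes of -0.61 (percentile 0 in both), with none counted of 15 and 18. The non-canonical Wnt list had a median of 0.02 (percentile 67.54). With each library rescaled to a total of 1000000, 16 genes were higher and 1 lower, 94.1% in place of 83.3%, and a pseudocount of 5 FPKM, with 0 higher and 1 lower, turned the balance.

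Against both E8.5 libraries, 283 genes were higher and 262 lower in the E10.5 liver. The balance depended on the setting, with 369 and 466 after rescaling to a total of 1000000 and 143 and 78 with a pseudocount of 5 FPKM. It also turned with a pseudocount of 0.1 FPKM (335 and 341), against foregut alone (308 and 358) and against medial foregut alone (311 and 374). Of 21 hepatic secreted genes 20 were higher, with medians of 5.92 against foregut and 6.09 against medial foregut (percentile 100 in both). The 12 highest included Alb, Ambp, Apoa2, F2, Fga, Gulo, Serpina6, Serpind1, Serpinf2 and Trf. Alb stood at 0.226 FPKM in foregut and 0.0231 in medial foregut. Gulo, encoding the last enzyme of vitamin C synthesis, stood at 0.741, 0.620 and 255 FPKM in foregut, medial foregut and liver. Of 13 hepatic transcription factors 7 were higher, and Cebpa stood at 0.282, 0.111 and 47.3 FPKM. On the lower side were heart genes: 14 of 15 cardiomyocyte genes were lower in liver, with medians of -3.48 and -4.51 (percentile 0 in both), and Myh7 stood at 486, 647 and 9.68 FPKM. Acta1, Actn2, Ankrd1, Myh6, Myl3, Nebl, Sox3 and Ttn were also among the 12 lowest; the Ttn locus covers 3.64% of the annotated span. Lower too were the retinoic acid binding protein gene Crabp1 (457, 325 and 2.18 FPKM), Foxh1 (27.7, 56.6 and 0.0731) and 7 of 13 anterior foregut factors, with medians of -2.71 and -3.05 (percentile 0 in both). The non-canonical Wnt list had medians of -0.53 and -0.57 (percentile 0 in both), with Wnt5a, Fzd2, Celsr1 and Sfrp5 of 42 lower. Wnt5a stood at 7.62, 12.8 and 0.582 FPKM. Of 13 Hedgehog genes 4 were lower, with medians of -2.24 and -1.71 (percentile 0 in both), and Shh stood at 10.2, 7.35 and 0.00678 FPKM.

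In ventral pancreas 242 genes were higher and 185 lower than in both E8.5 libraries, and in dorsal pancreas 179 were higher and 146 lower. The dorsal balance turned with a pseudocount of 5 FPKM, with 57 higher and 77 lower, and against medial foregut alone, with 220 and 230; a floor of 10 FPKM gave 119 each way. With the hepatic share subtracted, the ventral numbers were 192 and 226, 45.9% higher in place of 56.7%, a shift whose direction the subtraction fixes. Pancreatic progenitor factors were higher for 5 of 16 in ventral and 5 of 16 in dorsal pancreas, with medians against foregut of 1.56 and 1.097 (percentile 100 in both). Pdx1 stood at 0.945 FPKM in foregut and 0.444 in medial foregut. Endocrine genes were higher for 5 of 18 in ventral and 12 of 18 in dorsal pancreas; the difference between these numbers was not tested. Epithelial genes were higher for 8 of 25 in ventral and 1 of 25 in dorsal pancreas, with medians against foregut of 1.83 and 0.82 (percentile 100 in both). Hepatic secreted genes were higher for 15 of 21 in ventral and 5 of 21 in dorsal pancreas. The glucose transporter gene Slc2a2 stood at 0.0538 FPKM in foregut, 39.3 in ventral and 4.41 in dorsal pancreas. Cardiomyocyte genes were lower for 14 of 15 in ventral and 12 of 15 in dorsal pancreas. Actc1 stood at 1487 FPKM in foregut, 0.217 in ventral and 0.752 in dorsal pancreas. The non-canonical Wnt list lay close to its E8.5 level, with medians against foregut of -0.09 (percentile 0.53) in ventral and -0.05 (percentile 1.27) in dorsal pancreas; among the 28 members at a mean of 5 FPKM or more the percentiles were 6.12 and 8.75. Against medial foregut the ventral median was 0.003, and -0.09 under median-ratio rescaling. Wnt11 and Prickle1 of 42 were lower in ventral pancreas, and in dorsal pancreas Sfrp5 was lower and Daam2 higher.

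Genes higher in 1 library than in each of the other 4 numbered 102 for liver, 33 for dorsal pancreas, 20 for ventral pancreas, 2 for foregut and 1 for medial foregut. In liver these included Alb, Trf and Apoa1, and in ventral pancreas Sntg2, Hgf and Sox17. Hgf stood at 84.6 FPKM in ventral pancreas and at most 1.17 elsewhere. In dorsal pancreas they included Gcg, Barx1 and Hoxb8, in foregut Sox10 and Olig2, and in medial foregut the partial Aldoart2 locus.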

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

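Of the tests below, those of mixed liver cells and of low expression in ventral progenitors, that of RNA from the E8.5 libraries, that of scaling and the genes Tbx18 and Vsnl1 were chosen after the results were seen. The choice of lists that moved in opposite directions was also made after seeing the data.

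Loci without a gene name entered no comparison, yet held 26.7% of the summed FPKM in foregut, 27.93% in medial foregut, 27.27% in liver, 29.12% in ventral pancreas and 24.9% in dorsal pancreas. FPKM is per kilobase, so short loci weigh more in this sum, and it is no share of fragments or RNA. The most abundant unnamed locus spans 134 bp. In 3 lists the medians of liver and of both pancreatic libraries lay on opposite sides of both E8.5 libraries, each past the percentile limits; these differences were not tested. Lists that lay on opposite sides without passing the limits in every comparison, or that had no percentile, are not among them. The medians against foregut were -0.924 in liver, 1.556 in ventral and 1.097 in dorsal pancreas for pancreatic progenitor factors. For epithelial and endoderm genes they were -0.767, 1.832 and 0.824, and for the Notch pathway -0.854, 0.505 and 0.426. With the mean of the members, none of the 3 lists passed the limits in every comparison. Against medial foregut it ended the liver call for pancreatic progenitor factors (percentile 9.87) and the dorsal call for epithelial genes (percentile 95.58). For the Notch pathway it ended the liver call against medial foregut (percentile 3.06) and both pancreatic calls. The rule fixed beforehand for single genes asked for a difference of 2 or more from both E8.5 libraries in liver and the opposite in both pancreatic libraries, and 0 genes met it. Isl1 and Pyy were counted lower in liver and higher in dorsal pancreas than at E8.5, and were not counted in ventral pancreas.

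Hepatic secreted genes stood in the ventral pancreas library above their dorsal level, at a median share of 10.75% of the liver level over the dorsal base (quartiles 9.0% and 12.75%), with Apoc2 lowest at 4.874% and Ambp at 59.67%, Vtn at 49.08% and Ttr, a locus on the other strand, at 59.89% far above a common share. Mixed cells of the liver library as a whole are argued against, because 10 leukocyte and cardiac genes had a median excess of -0.16 times the hepatic share, with 2 above dorsal pancreas. An admixture of hepatic epithelium alone may account for part of the pattern: of 7 other liver genes, 71.4% had a share within a factor of 2, short of the 75% set beforehand, and the 2 outside it were Reln at 38.94% and the merged H2 locus at 0.03874%. That outcome rests on the merged H2 locus, whose source gene is unknown: without it, a choice made after its value was seen, 83.33% of 6 genes lay within the factor. For the secreted genes, low expression in ventral progenitors themselves cannot be told apart from it, since the quartiles differed by a factor of 1.42, between the bounds that would decide. The explanation also named hepatic transcription factors, which this test left out. Of 13 measured, 7 stood lower in liver than in ventral pancreas and 6 higher, with a median difference of -0.14. A share of liver RNA alone cannot put a gene above its liver level, so it does not account for those 7. As 4 of the 13 are also on another list, this does not decide for the secreted genes.

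Cardiac genes stood higher in the liver library than in both pancreatic libraries. RNA carried over from the E8.5 libraries is argued against, since the liver to foregut ratio of 10 abundant cardiac genes ranged over a factor of 136.0, or 10.96 without Myl3. Heart muscle at the venous inflow next to the liver could be the source: Hcn4 stood at 5.00 FPKM in liver against 1.0998 and 2.55 in the pancreatic libraries and Shox2 at 10.8 against 7.27 and 0.503. The smaller ratio was 1.49 where 4 had been required, so this stays open. Tbx18 (10.45, 1.78 and 0.108 FPKM) and Vsnl1 (8.10, 0.0574 and 0.269) were higher in liver. Both were chosen after their values were seen, and Tbx18 is also on the mesothelium and septum transversum list, so neither decides the question.

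The non-canonical Wnt list was lower in liver. Scaling of the libraries may contribute a part. Median-ratio rescaling left the median over all genes at -0.032 against ventral and -0.031 against dorsal pancreas. It moved the list's medians from -0.51 to -0.401 against ventral and from -0.57 to -0.45 against dorsal pancreas. The middle 95% of medians over resampled members ran from -0.648 to 0.005 against ventral and from -0.884 to -0.291 against dorsal pancreas. The upper end was positive against ventral pancreas, so the bounds set for this test did not decide. That interval describes the spread over members and does not measure scaling. A smaller share of epithelial cells in the liver library may contribute and cannot be told apart. The prediction asked for Krt8, Krt18 and Krt19 to be lower by at least the list's median difference against both pancreatic libraries. Krt19 met it, at 2.32 FPKM in liver against 24.1 in ventral and 12.2 in dorsal pancreas. Krt8, at 121 against 225 and 137, fell short against dorsal pancreas. Krt18, at 183 against 239 and 101, fell short against ventral pancreas and was higher in liver than in dorsal pancreas, by 0.851. A difference between hepatic and pancreatic progenitors themselves, which the design names, remains untested.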

How the results depend on the processing

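No paired analysis was possible because each group has 1 library and the result comes from no test; leaving out a replicate was likewise impossible. Depth in reads is unknown and limits what low values can show. The filters on loci and the hepatic subtraction were chosen after seeing the data. Unless a value shows otherwise, the cause was not tested. A pseudocount of 5 FPKM lowered the counts by construction: liver against pancreas 56 higher and 36 lower, ventral against dorsal 34 and 26, foregut against medial foregut 0 and 1, liver against E8.5 143 and 78, ventral pancreas against E8.5 75 and 74, dorsal pancreas against E8.5 57 and 77, and genes high in 1 library 0 in foregut, 47 in liver, 8 in ventral, 9 in dorsal pancreas and 65 in all. A pseudocount of 0.1 FPKM gave 8 higher and 3 lower for foregut against medial foregut, and 4 genes high in foregut, 3 in medial foregut, 38 in ventral and 52 in dorsal pancreas. Rescaling to a total of 1000000, which raises every value and so weakens pseudocount and floor, gave 415 lower in liver than in pancreas, 192 and 176 for ventral against dorsal, 16 higher in foregut, 466 lower in liver than at E8.5, 468 and 291 for ventral and 343 higher for dorsal pancreas, and 8, 39 and 60 genes high in foregut, ventral and dorsal pancreas. A floor of 10 FPKM gave 3 higher in foregut, 119 higher and 119 lower in dorsal pancreas than at E8.5 and 1 high in foregut alone; leaving out loci listed at 0 also gave 1 there. Against 1 library alone, liver had 342 lower than ventral, and 262 higher and 414 lower than dorsal pancreas; against medial foregut alone ventral pancreas had 297 higher and 280 lower, and dorsal pancreas 220 and 230. Leaving out unstranded, short and joined loci, or loci on the other strand or partial, left 0 lower in foregut and 0 high in medial foregut, since the Aldoart2 locus is both short and partial. For hepatic transcription factors in liver minus ventral pancreas, the mean was 0.235, members at a mean of 5 FPKM or more gave 0.685 and the strand and span filter 0.273, each past the percentile limit and of the other sign than the median. The non-canonical Wnt list against ventral pancreas gave -0.312, inside the limits, among members at a mean of 5 FPKM or more, and the canonical list 0.144, past them, under the strand and span filter. In 7 cases a called list median changed sign. With members at a mean of 5 FPKM or more, the mesothelium list gave -0.719 and -0.859 in liver minus ventral and dorsal pancreas, and in dorsal pancreas the anterior foregut list gave 0.861 against foregut and 0.673 against medial foregut and the retinoic acid list 0.254 against medial foregut. Also in dorsal pancreas against medial foregut, the mean gave 0.211 for Frizzled receptors and the strand and span filter 0.178 for fibroblast-like mesenchyme. List percentiles test rescaling weakly, because the random lists are rescaled with the list; 4 list calls were lost and 1 gained under median-ratio rescaling. Of the named genes' differences, 3658 kept their side of the size rule under median-ratio rescaling, 25 fell short and 17 passed.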

Other observations

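Glycolysis and hypoxia genes had medians of -0.15 (percentile 9.61) for liver minus ventral, 0.59 (percentile 99.96) for liver minus dorsal and 0.64 (percentile 100) for ventral minus dorsal pancreas. Of 17 members, the glucose transporter gene Slc2a3 was counted higher in ventral than in dorsal pancreas (67.8 against 9.13 FPKM). Lactate dehydrogenase gene Ldha stood at 973 FPKM in liver, 783 in ventral and 324 in dorsal pancreas. Slc2a1 stood at 251 FPKM in foregut against 40.2 in liver. Ribosomal protein genes had medians of 0.35 (percentile 98.61) and 0.44 (percentile 99.8) in liver minus ventral and dorsal pancreas, with 0 of 26 counted. Cell cycle genes had medians of 0.10 and 0.01 there, inside the middle 95%, and Cdkn1a, a cell cycle inhibitor, was higher in dorsal pancreas than at E8.5 (30.7 against 6.16 and 5.51 FPKM). Immediate early genes (0.04 and -0.24) and widely expressed genes (0.15 in both) also lay inside.

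Blood and other cell types gave mixed values. Of 5 measured erythroid genes, the embryonic globin gene Hbb-y was higher in ventral (111 FPKM) than in dorsal pancreas (24.4); the list's medians in liver minus ventral and dorsal pancreas were -0.77 and -0.15, inside the middle 95%. Slc4a1, a red cell membrane gene at a locus with 18.4% of the annotated span, stood at 28.5 against 1.56 FPKM. Neural tube genes had medians of -0.73 (percentile 10.17) and -0.96 (percentile 1.11) in liver minus ventral and dorsal pancreas, and neural crest genes -0.21 (percentile 78.47) and -1.02 (percentile 2.25). A pseudocount of 0.1 FPKM moved the neural tube list to percentile 2.42 against ventral and 4.66 against dorsal pancreas, unmatched random lists put it at 1.15 against ventral pancreas, and the mean moved the neural crest list to 17.99. Midgut and hindgut genes and genes of the paraxial mesoderm, notochord and primitive streak had 4 measured members each and no percentile, with 0 counted in liver against pancreas; the medians against ventral and dorsal pancreas were -0.27 and 0.02 for the first list and -0.47 and -1.32 for the second. Dlk1, a Notch-related gene of fetal liver, stood at 57.4 FPKM in foregut, 66.7 in medial foregut, 2377 in liver, 1718 in ventral and 485 in dorsal pancreas. Of the X-inactive and Y-linked transcripts, Xist stood at 58.4 FPKM in foregut, 49.4 in medial foregut, 6.96 in liver, 119 in ventral and 64.0 in dorsal pancreas, and Eif2s3y at 15.7, 17.0, 29.1, 13.9 and 13.4. Xist was counted lower in liver than in both pancreatic and both E8.5 libraries, and Eif2s3y was highest in liver. Comparisons with liver are thus not balanced for these sex-linked transcripts.

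Among unnamed loci, an unstranded one on chromosome 14 (20110659 to 20110793 in mm9) stood at 5672 FPKM in foregut, 12990 in medial foregut, 7097 in liver, 16362 in ventral and 7012 in dorsal pancreas. Unnamed loci on chromosomes 6 and 3 were also higher in medial foregut than in foregut, by 2.04 and 2.02 times, and in ventral than in dorsal pancreas, by 2.81 and 2.83 times. A locus on chromosome 17 rose likewise, by 1.85 and 2.72 times. The other most abundant unnamed loci reached at most 1.08 and 1.31 times, at a second locus on chromosome 6.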
